A study of Arabidopsis thaliana with 12 samples.

How the data were processed

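The series held 12 mRNA sequencing libraries from Arabidopsis thaliana seedlings: Col-0 and ein2-5, each with and without glucose, 3 libraries per group. Per the labels, seedlings grew for 4 days in liquid medium without glucose and were treated for 2 h. The treatment field of the labels names glucose for all 12 samples, whereas the description of the design gives treatment with or without 15 mM glucose, so the groups were taken from the sample titles. The labels do not say whether the 3 libraries of a group came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical in part.

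A single table of 19522 genes was used, with a value column for each library and no unused value column. The authors aligned the reads with TopHat to the TAIR10 genome and counted them with HTSeq, with no version or strand setting given. The deposited values are in CPM, reads scaled to 1000000 per library, a unit read from the values since the header does not name it. Each column summed to 1000000 over the listed genes, and 100% of the 234264 values were whole multiples of the value of a single read, within 0.01 reads. Between 11470134 and 17461274 reads per library were recovered in this way, and a gene at 3 reads, taken as the floor of each library, had 0.172 to 0.262 CPM. Of the genes, 239 stood at 0 in at least 1 library, and the lowest maximum of any gene was 1.06 CPM, so genes low in every library had been removed before deposition. No scaling for composition was recorded. TMM factors computed from the recovered reads lay between 0.8875 and 0.9216 in Col-0 −Glc and between 0.9768 and 1.0753 in the other groups.

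Genes were joined by locus code to the RefSeq annotation of TAIR10.1 for symbols, product names and coordinates. Of the locus codes 19352 were matched and 170 were not, and 8497 genes had a symbol other than the locus code. The table held 112 chloroplast and 38 mitochondrial genes, which were kept. The share of reads of the 10 most abundant genes of each library lay between 5.34% and 8.49%, that of chloroplast genes between 1.06% and 4.78%, and that of mitochondrial genes between 0.208% and 3.86%. Near-identical copies of a gene share reads in ways that HTSeq settings decide, and those settings were not given.

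The test planned for counts was edgeR's quasi-likelihood test. Since the table held CPM, the test planned for normalized values was used instead: limma-trend on log2(CPM + 1), with a mean for each of the 4 groups, all 12 libraries in a single fit and 8 residual degrees of freedom. No filter was applied. P-values were adjusted by the Benjamini-Hochberg method over 19522 genes, with a threshold of 0.05, and counts at an absolute log2 fold change of at least 1 were added. The contrasts were glucose against none in each genotype, ein2-5 against Col-0 in each condition, and the difference of the glucose responses, ein2-5 minus Col-0. R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used.

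The size of the response was compared over the genes past the threshold in the average glucose response with an absolute log2 fold change of at least 1, for rises and falls separately. Its two-sided p came from an exact permutation of the genotype labels within each glucose condition, 400 relabellings, of which the smallest possible p was 0.005. That permutation assumes no genotype difference in either condition, so its p does not measure a difference of the responses alone. For the overlap of contrasts that share libraries, all 12 libraries were simulated 20 times as unchanged. Each gene varied around its mean over the 12 libraries with its fitted spread, independently of other genes.

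Gene lists, 20 with 387 members (386 loci), were fixed together with the tests, thresholds and most other settings tried, before the data were examined. Of the members 367 were measured, and 10 carried another symbol in the reference. The plan was to leave out a member whose locus carried another gene's name. No member was removed on that ground, and the measured ones were tested with their lists. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 20 lists of a contrast, and again with a correlation estimated for each list. The estimates lay between −0.014 for the ethylene response genes and 0.933 for the seed storage and late embryo genes. List medians are given relative to the median of all genes where scaling matters. Named genes were the 10 with the largest rise and the 10 with the largest fall per contrast among those past the threshold, with a symbol, a mean of at least 5 CPM in the higher group, and no overlap between the libraries of the groups, which chance gives for 10% of genes at 3 against 3. For the difference of the responses no such separation was asked. EIN2 and up to 4 members per list with the largest change were added.

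Replicates of a group had Pearson r between 0.9688 and 0.9937 on log2(CPM + 1), and the chi-square per gene between pairs of replicates lay between 6.46 and 71.6, so no library repeated another. The test was also tested on simulated data with 200 changed genes among 19522. For the glucose response in Col-0 limma recovered 19.4%, 80.6% and 95.5% of genes changed by 0.5, 1 and 2 on the log2 scale, with 4.4% false calls. For the difference of the responses it recovered 4.5%, 43.3% and 86.4%, with 2.2% false calls. The measured data gave many more calls than 200, 11775 for glucose in Col-0 and 3678 for the difference of the responses. Recovery and false calls after adjustment depend on how many genes change. These rates therefore hold for the simulated setting only and do not measure the performance of the test on the measured contrasts.

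Other settings chosen at that time were RLE size factors, the DESeq2 Wald test, a filter of 1 CPM in 3 libraries, no filter beyond 1 count, a fit to only the 2 groups compared, a replicate block, organelle genes left out, a pseudocount of 0.1, and each library left out in turn. Added after the data were seen were edgeR's quasi-likelihood test on the recovered reads with 19522 genes kept by its filter, limma after TMM scaling, the 3 libraries with many more seed transcripts than others of their group left out (Col-0 −Glc 1, ein2-5 +Glc 2 and 3, the seed-rich libraries), and the mean log2 level of the seed list as a covariate. No sample was left out of the reported fits.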

Results

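Messenger RNA was sequenced from whole Arabidopsis thaliana seedlings of the wild type Col-0 and of ein2-5, a mutant of EIN2, the membrane protein that carries the ethylene signal from the receptors to the nucleus. Seedlings had grown for 4 days in liquid medium without glucose and were then given 15 mM glucose or none for 2 h, which makes 4 groups of n = 3 libraries. The table held 19522 genes in 12 libraries, and between 11470134 and 17461274 reads per library were recovered from its values. Means are given in CPM, reads scaled to 1000000 per library, ± SD over n = 3 libraries, and fold changes as log2 differences ± SE on the log2(CPM + 1) scale, which understates the change of low genes.

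EIN2 itself (AT5G03280, chromosome 5, 787428 to 793404 in TAIR10.1) served as a check of the labels. It lay between 124.962 and 137.055 CPM in Col-0 −Glc and between 104.848 and 117.685 CPM in Col-0 +Glc. In ein2-5 it lay between 43.38 and 60.215 CPM without glucose and between 48.474 and 50.297 CPM with glucose, so every library followed its genotype label. The genotype difference was −1.27 ± 0.107 without glucose (limma adjusted p = 1.61e-06) and −1.18 ± 0.107 with glucose (limma adjusted p = 3.44e-06). Glucose gave EIN2 a log2 difference of −0.19 in Col-0 (limma adjusted p = 0.136) and −0.10 in ein2-5 (limma adjusted p = 0.466), neither past the threshold as deposited. After TMM scaling the differences were −0.40 in Col-0 and −0.16 in ein2-5, and in edgeR −0.40 and −0.17. The size of the fall in Col-0 thus depended on the scaling, and a lack of change cannot be concluded.

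**Figure D1:**
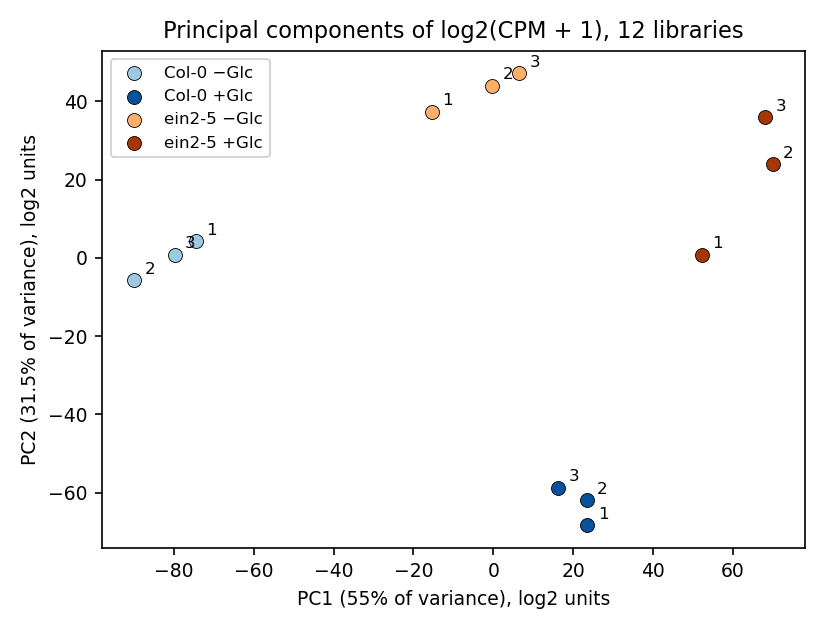
Scores of the 12 libraries on the principal components of log2(CPM + 1), in log2 units; points are libraries, colours the 4 groups and digits the replicate numbers. The components hold 55% and 31.5% of the variance, and the 4 groups occupy separate areas.

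The glucose response of the wild type asked what sugar recovery changes in seedlings starved of it. All 28 measured genes of the sugar starvation list, which the energy sensor kinase SnRK1 switches on when carbon runs short, fell within 2 h in Col-0. All 25 measured ribosome biogenesis genes and 24 of 26 measured DNA replication genes rose. The nitrate reductases NIA1 (AT1G77760) and NIA2 (AT1G37130) dropped from 2017 ± 52.6 to 36.9 ± 16.3 CPM and from 2392 ± 111 to 66.4 ± 22.4 CPM. GPT2 (AT1G61800), which moves glucose 6-phosphate into plastids, went from 0.591 ± 0.237 to 58.6 ± 13.2 CPM, a log2 difference of 5.22 ± 0.185 (limma adjusted p = 2.66e-10).

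The starvation genes had a median log2 change of −4.46 relative to that of all genes, and all 28 also fell when adjusted over the list alone. Camera gave the list adjusted p = 2.81e-27, and adjusted p = 0.078 with an estimated correlation. ASN1 (AT3G47340), the asparagine synthetase induced in darkness, fell from 1214 ± 64.2 to 48.4 ± 13.0 CPM. The senescence marker SEN1 (AT4G35770) had a log2 difference of −5.25 ± 0.191, the beta-galactosidase gene BGAL4 (AT5G56870) of −5.21 ± 0.141, and the trehalose phosphate synthase family gene TPS11 (AT2G18700) of −5.43 ± 0.349. Enzymes of branched-chain amino acid breakdown were among them, with BCAT-2 (AT1G10070) at −5.80 ± 0.263 and MCCA (AT1G03090) at −5.23 ± 0.169. Autophagy genes, whose products degrade cell contents for reuse, fell in 18 of 26 cases, and 8 did not pass; the count adjusted over the list alone was also 18. Their camera adjusted p was 2.9e-08, and adjusted p = 0.314 with an estimated correlation. The ubiquitin-like autophagy proteins ATG8E (−3.36 ± 0.178) and ATG8F (−2.46 ± 0.117) fell furthest.

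Among the ribosome biogenesis genes all 25 rose, also when adjusted over the list alone, by a median 1.66 above that of all genes (camera adjusted p = 1.25e-11; adjusted p = 0.437 with an estimated correlation). The small nucleolar ribonucleoprotein NOP56 (AT1G56110) rose by 2.38 ± 0.125, the rRNA methyltransferase fibrillarin FIB2 (AT4G25630) by 2.31 ± 0.216, and the nucleolin NUC-L1 (AT1G48920) by 2.03 ± 0.123, from 265 ± 24.8 to 1079.9 ± 74.99 CPM. Cytosolic ribosomal protein genes rose in 29 of 30 cases, adjusted over the list alone 29, with a median 0.58 above that of all genes. Camera gave them adjusted p = 5.15e-06, and adjusted p = 0.592 with an estimated correlation. Of the DNA replication genes 24 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 4.12e-07; adjusted p = 0.437 with an estimated correlation). The sliding clamp PCNA1 rose by 1.86 ± 0.158 and the helicase subunit MCM2 by 1.74 ± 0.163, whereas the transcription factor E2FB, listed under the symbol E2F1, fell by 0.32. The mitosis genes did not follow as a list: 3 rose, 2 fell and 13 did not pass as deposited, 1 and 1 adjusted over the list alone, and 1 rose and 6 fell after TMM scaling (camera adjusted p = 0.34).

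Genes of the glycolysis list rose in 15 of 16 cases, adjusted over the list alone 15 (camera adjusted p = 0.000142, and 0.437 with an estimated correlation). They were led by the phosphoenolpyruvate carboxylase PPC1 at 1.48 ± 0.099. The list as fixed also holds PPC3 and the glucose 6-phosphate dehydrogenases G6PD5 and G6PD6. Like PPC1, these are not enzymes of glycolysis itself. Flavonoid and anthocyanin genes rose in 9 of 14 cases and fell in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.0291; adjusted p = 0.592 with an estimated correlation). The flavonol synthase FLS1 rose by 2.03 ± 0.108 and the anthocyanin regulator PAP1 by 2.12 ± 0.223. Light harvesting and RuBisCO small subunit genes fell in 6 of 20 cases and 14 did not pass, adjusted over the list alone 5 fell, and 9 fell after TMM scaling and 12 in edgeR (camera adjusted p = 0.00682; adjusted p = 0.619 with an estimated correlation). The LHCB1 copies CAB2 (−0.71 ± 0.206) and LHB1B1 (−0.83 ± 0.214) were among those that fell, although near-identical copies leave the split of their reads uncertain.

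The remaining lists did not pass camera in this contrast. Of 17 starch, sucrose and sugar transport genes 10 rose and 3 fell (camera adjusted p = 0.2), with the granule-bound starch synthase GBSS1 up by 3.16 ± 0.179 and the sucrose transporter SUC1 up by 2.61 ± 0.118. Of 17 nitrate genes 6 rose, 6 fell and 5 did not pass (camera adjusted p = 0.718): NIA1 and NIA2 changed by −5.82 ± 0.251 and −5.20 ± 0.214, whereas the transporter gene NRT1.1 rose by 2.54 ± 0.127. Ethylene response genes, targets of the transcription factor EIN3, rose in 5 of 17 cases and fell in 4 as deposited, and 3 rose and 6 fell after TMM scaling (camera adjusted p = 0.256). Among 17 genes of ethylene synthesis and signalling 4 rose and 7 fell (camera adjusted p = 0.199). Of 21 expansin, xyloglucan and cellulose genes 12 rose and 5 fell (camera adjusted p = 0.718). Auxin response genes rose in 8 of 13 cases as deposited, and 6 rose and 3 fell after TMM scaling (camera adjusted p = 0.177). Of 14 root and root hair markers 8 rose and 1 fell as deposited, and 7 rose and 6 fell after TMM scaling (camera adjusted p = 0.823). Touch and wounding genes rose in 3 and fell in 3 of 14 cases, 2 and 4 after TMM scaling (camera adjusted p = 0.256), low oxygen genes rose in 2 and fell in 1 of 10 (camera adjusted p = 0.958), and clock genes rose in 3 and fell in 5 of 13 (camera adjusted p = 0.14). None of the 11 seed storage and late embryo genes passed (camera adjusted p = 0.138). In the ethylene response, ethylene signalling, mitosis and nitrate lists the median, the mean and the camera direction did not share a sign.

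Among the named genes outside the lists, the heat stress regulator HSFA2 (AT2G26150) rose by 5.34 ± 0.394, the chaperone genes HSP70 (AT3G12580) and HSP90.1 (AT5G52640) by 4.63 ± 0.34 and 4.44 ± 0.381, and the sulfate reduction enzyme APR1 (AT4G04610) by 4.55 ± 0.347. FRK1 (AT2G19190), a receptor kinase induced by flagellin, rose by 4.30 ± 0.225, the transporter gene ABCG8 (AT5G52860) by 4.03 ± 0.129, CRK12 (AT4G23200), a cysteine-rich receptor-like kinase, by 3.73 ± 0.276, the purple acid phosphatase PAP17 (AT3G17790) by 3.63 ± 0.342, and the methionine synthase MS2 (AT3G03780) by 3.598 ± 0.146. The largest falls outside the lists were in BT1 (AT5G63160), a BTB and TAZ domain protein, at −6.09 ± 0.212, and in GAT1_2.1 (AT1G15040) at −5.86 ± 0.233. They were followed by the threonine aldolase THA1 (AT1G08630) at −5.64 ± 0.164, the myo-inositol oxygenase MIOX4 (AT4G26260) at −5.56 ± 0.134, and the cytochrome P450 CYP81D11 (AT3G28740) at −5.43 ± 0.294. Limma adjusted p for these 14 genes lay at or below 1.01e-06.

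In limma 7925 genes were higher and 3850 lower with glucose, and 2371 and 1179 of them changed at least by 1 on the log2 scale. The median of all genes in this contrast was 0.19 as deposited. After TMM scaling, which centres the fold changes, it was 0.01, and 5969 genes were higher and 5842 lower, so 67.3% of the calls were higher as deposited and 50.5% after TMM.

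**Figure D2:**
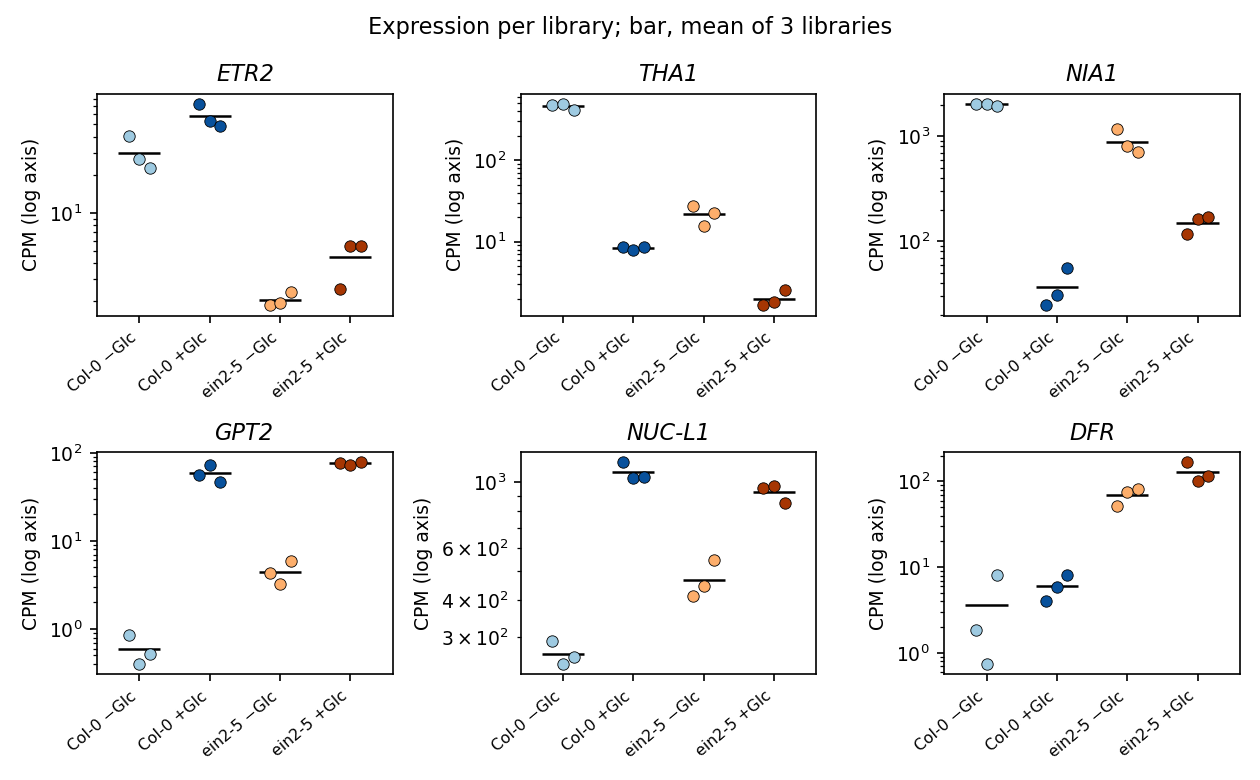
CPM on log axes in each library for 6 genes, points for libraries and bars for the mean of 3 libraries per group. ETR2 and DFR separated the genotypes in both conditions, THA1 and NIA1 were lower with glucose, and GPT2 and NUC-L1 were higher with glucose in both genotypes.

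The same contrast in ein2-5 asked what glucose does when the ethylene signal is blocked. The 8 lists that passed camera in Col-0 also passed here, in the same directions. All 28 starvation genes fell, with a median −2.80 relative to all genes (camera adjusted p = 6.34e-29; adjusted p = 0.0659 with an estimated correlation), and all 25 ribosome biogenesis genes rose, with a median of 0.80 relative to all genes (camera adjusted p = 2.02e-11; adjusted p = 0.377 with an estimated correlation). Adjusted over the list alone these counts were also 28 and 25. ASN1 fell from 178 ± 55.1 to 5.70 ± 1.59 CPM, GPT2 rose from 4.48 ± 1.37 to 76.2 ± 2.69 CPM, and NUC-L1 rose from 469 ± 70.0 to 927 ± 65.1 CPM.

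Autophagy genes fell in 14 of 26 cases, adjusted over the list alone 16 (camera adjusted p = 6.81e-07; adjusted p = 0.377 with an estimated correlation). Ribosomal protein genes rose in 28 of 30, adjusted over the list alone 28 (camera adjusted p = 1.42e-06; adjusted p = 0.52 with an estimated correlation). DNA replication genes rose in 24 of 26 cases, adjusted over the list alone 24 (camera adjusted p = 1.46e-08; adjusted p = 0.377 with an estimated correlation). Glycolysis genes rose in 13 of 16, adjusted over the list alone 14 (camera adjusted p = 0.000144; adjusted p = 0.377 with an estimated correlation), and flavonoid genes rose in 11 of 14 and fell in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.000218; adjusted p = 0.377 with an estimated correlation). Light harvesting genes fell in 9 of 20, adjusted over the list alone 9 (camera adjusted p = 0.000218; adjusted p = 0.52 with an estimated correlation). Clock genes fell in 5 of 13 and rose in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.00894; adjusted p = 0.412 with an estimated correlation). Mitosis genes passed in 1 of 18 cases, SYP111, also known as KNOLLE, the syntaxin of the cell plate, at −0.49 ± 0.121 (camera adjusted p = 0.965).

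The named genes with the largest rises were the high-affinity nitrate transporter NRT2:1 (AT1G08090) at 4.06 ± 0.12, GPT2 at 3.85 ± 0.185, APR1 at 3.23 ± 0.347 and HSP90.1 at 2.94 ± 0.381. HSFA2 rose by 2.92 ± 0.394, HSP70 by 2.76 ± 0.34 and PAP17 by 2.29 ± 0.342. The sulfur deficiency gene LSU2 (AT5G24660) rose by 2.63 ± 0.357, APR3 (AT4G21990) by 2.30 ± 0.295, and the small heat shock gene HSP17.6II (AT5G12020) by 2.28 ± 0.497. The largest falls were in ASN1 at −4.72 ± 0.23, BT1 at −3.94 ± 0.212, SEN1 at −3.82 ± 0.191 and MIOX4 at −3.76 ± 0.134. The acyl-CoA binding protein gene ACBP3 (AT4G24230) followed at −3.72 ± 0.276, PP2-A13 (AT3G61060) at −3.66 ± 0.191, the DnaJ chaperone J8 (AT1G80920) at −3.603 ± 0.301, and BT2 (AT3G48360) at −3.55 ± 0.635. MIOX2 (AT2G19800) stood at −3.53 ± 0.181 and BT5 (AT4G37610) at −3.52 ± 0.316. Limma adjusted p for these 20 genes lay between 8.17e-10 and 0.00269.

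In limma 5168 genes were higher and 3204 lower, 546 and 599 of them at least by 1 on the log2 scale. Without ein2-5 +Glc 1, which had the fewest seed reads of the ein2-5 libraries, 5329 were higher and 3675 lower. Without the 3 libraries that held many more seed reads than others of their group (Col-0 −Glc 1, ein2-5 +Glc 2 and 3; below, the seed-rich libraries), 2683 were higher and 1729 lower, and the light harvesting list no longer passed (camera adjusted p = 0.0783). Of the genes called in Col-0 and ein2-5, 4513 were higher in both, 2425 lower in both and 66 opposite, against 2098, 632 and 2320 for independent lists. Without the 3 seed-rich libraries 4077 were called the same way. The fit without the seed-rich libraries kept ein2-5 +Glc 1 alone in its group, so its fewer calls cannot be put down to seed reads. Across genes, which are not independent replicates, the fold changes of Col-0 and ein2-5 over all 12 libraries had Pearson r = 0.831.

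**Figure D3:**
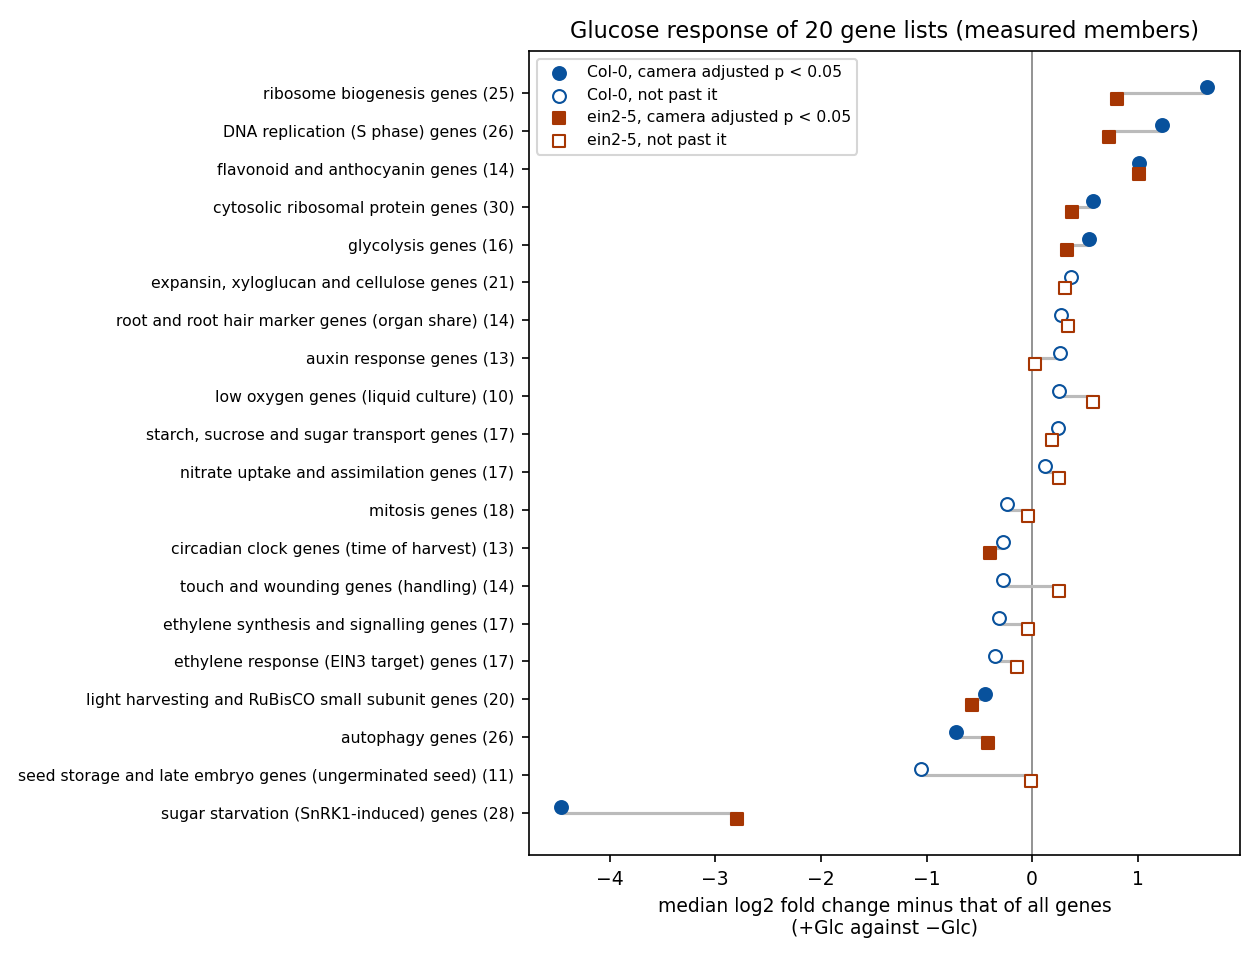
Median log2 fold change with glucose for the 20 gene lists, minus the median of all genes; circles Col-0, squares ein2-5, filled where the camera adjusted p lay below 0.05, with the number of measured members in brackets. The starvation genes stood at −4.46 in Col-0 and −2.80 in ein2-5, the ribosome biogenesis genes at 1.66 and 0.80.

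Whether the mutant responded differently was tested by the difference of the responses, ein2-5 minus Col-0. The starvation genes fell less in ein2-5: 21 of 28 had a positive difference, 24 adjusted over the list alone, with a median 1.75 above that of all genes (camera adjusted p = 6.26e-25; adjusted p = 0.1 with an estimated correlation). The ribosome biogenesis genes rose less in ein2-5, with a negative difference in 24 of 25, also 24 adjusted over the list alone, and a median of −0.85 relative to all genes (camera adjusted p = 3.23e-14; adjusted p = 0.431 with an estimated correlation). NIA1 was among the genes that differed: it ended at 36.9 ± 16.3 CPM in Col-0 and at 150.3 ± 27.9 CPM in ein2-5, after starting at 2017 ± 52.6 and 892 ± 241 CPM, a difference of 3.27 ± 0.355 (limma adjusted p = 0.000105).

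Among the starvation genes, BGAL4 had a difference of 2.45 ± 0.2, BCAT-2 of 2.41 ± 0.372, GDH2, a glutamate dehydrogenase, of 2.15 ± 0.2, and the hexose transporter STP1 of 2.05 ± 0.199. ASN1 did not follow them, with −0.06 ± 0.325 (adjusted p = 0.917). Autophagy genes had a positive difference in 7 of 26, also 7 adjusted over the list alone (camera adjusted p = 6.88e-05; adjusted p = 0.431 with an estimated correlation), with ATG8F at 1.04 ± 0.166. Among ribosome biogenesis genes PUM24 stood at −1.41 ± 0.196 and NOP56 at −1.40 ± 0.177. DNA replication genes had a negative difference in 10 of 26, 17 adjusted over the list alone and 2 after TMM scaling (camera adjusted p = 0.000528; adjusted p = 0.546 with an estimated correlation), with PCNA1 at −0.85 ± 0.224. Nitrate genes had a positive difference in 4 of 17 and a negative one in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.00314; adjusted p = 0.546 with an estimated correlation). NIA2 stood at 2.94 ± 0.302 and NRT1.1 at −0.92 ± 0.18. NRT2:1 had 1.29 ± 0.17 in limma but 0.49 in edgeR, since it started near the floor (0.2 and 0.582 CPM), where the pseudocount of 1 compresses the fold change.

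Ribosomal protein genes had a negative difference in 5 of 30, 4 adjusted over the list alone and 2 after TMM scaling (camera adjusted p = 0.0236; adjusted p = 0.686 with an estimated correlation). Glycolysis genes had a negative difference in 4 of 16, also 4 adjusted over the list alone (camera adjusted p = 0.0236; adjusted p = 0.546 with an estimated correlation). These 2 calls were not robust: after TMM scaling their adjusted p were 0.0816 and 0.0791. The ribosomal protein call also ended without Col-0 −Glc 2 (0.0656), ein2-5 −Glc 2 (0.15), ein2-5 −Glc 3 (0.072) or ein2-5 +Glc 1 (0.201), and the glycolysis call without ein2-5 −Glc 3 (0.072) or without the 3 seed-rich libraries (0.14). The other 13 lists did not pass, the auxin response genes at camera adjusted p = 0.0568 with 5 of 13 members lower, 3 after TMM scaling, and the ethylene response genes at 0.332 with 3 of 17 higher and 2 lower.

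Genes whose response was more positive in ein2-5 included CYP81D11 at 3.41 ± 0.416, PPDK (AT4G15530), a pyruvate orthophosphate dikinase, at 3.23 ± 0.368, the beta-xylosidase gene BXL2 (AT1G02640) at 3.04 ± 0.584, and THA1 at 2.73 ± 0.231. PSK2 (AT2G22860), a phytosulfokine precursor, stood at 2.66 ± 0.239, the auxin glucosyltransferase IAGLU (AT4G15550) at 2.55 ± 0.261, ORP4C (AT5G57240) at 2.48 ± 0.328, and the vacuolar malate transporter TDT (AT5G47560) at 2.47 ± 0.227. In ein2-5 PSK2 had means of 0.214 CPM without and 0.235 CPM with glucose, at the floor, so a fall there could not be seen. Genes with a more negative one included NRT2.6 (AT3G45060) at −3.31 ± 0.506, the peptide hormone gene RGF9 (AT5G64770) at −2.80 ± 0.396, ABCG8 at −2.43 ± 0.183 and HSFA2 at −2.42 ± 0.557. SHB1 (AT4G25350) stood at −2.41 ± 0.312, CRK5 (AT4G23130) at −2.34 ± 0.331 and CSLA11 (AT5G16190) at −2.27 ± 0.22. Limma adjusted p for these lay between 2.32e-05 and 0.00952. FRK1 rose to 22.7 ± 7.45 CPM in Col-0 and reached 0.35 ± 0.341 CPM in ein2-5, a difference of −3.93 ± 0.318 in limma (adjusted p = 2.69e-05) that did not pass in edgeR (0.483) or DESeq2 (0.105). CRK12, at −2.22 ± 0.39 (limma adjusted p = 0.00201), did not pass in edgeR (0.0695). The nitrate transporter gene NRT2.5 (AT1G12940) was listed at 0 in 3 of 3 Col-0 −Glc libraries and at 6.76 ± 0.728 CPM in Col-0 +Glc, at least 31.5-fold higher against a floor of 3 counts per library. In ein2-5 its means were 0.023 ± 0.04 and 0.157 ± 0.137 CPM, and its difference of −2.78 ± 0.192 (limma adjusted p = 2.04e-05) did not pass in edgeR (0.081).

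Across all genes 1072 had a more positive and 2606 a more negative response in ein2-5 in limma, and 1873 and 1794 after TMM scaling, which moved the median of all genes from −0.11 to 0.02. Without the 3 seed-rich libraries the counts were 538 and 1276. Of the 3678 genes, 2919 responded in the same direction and more in Col-0, 65 in the same direction and more in ein2-5, and 694 had fold changes of opposite sign, of which 66 passed in both genotypes. Over the 1285 genes that rose on average over both genotypes by at least 1 on the log2 scale, the response was smaller in ein2-5 for 1203, with a median difference of −0.80 (two-sided exact permutation p = 0.04, 400 relabellings of genotypes within condition, smallest possible 0.005). The 846 genes that fell had a median difference of −0.68 in the size of the fall, smaller in ein2-5 for 750 (exact permutation p = 0.015; under RLE scaling −0.74 with exact permutation p = 0.05, not past the threshold). Over all genes past adjusted p in the average response, with no minimum fold change, the medians were −0.30 for rises (exact permutation p = 0.095) and −0.17 for falls (exact permutation p = 0.19), neither past the threshold. The p of the rises was 0.065 without Col-0 +Glc 1, 0.055 without ein2-5 −Glc 3 and 0.08 without ein2-5 +Glc 1. With the replicate block the rises kept −0.80, with exact permutation p = 0.125, not past the threshold. The permutation assumes no genotype difference in either condition, so its p does not measure a difference of the responses alone.

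The genotype comparison without glucose asked what loss of EIN2 changes in starved seedlings. Ethylene response genes were lower in ein2-5: 13 of 17 lower, 2 higher and 2 not past the test, the same when adjusted over the list alone (camera adjusted p = 5.89e-08; adjusted p = 0.00577 with an estimated correlation). The ethylene receptor ETR2 (AT3G23150) stood at 29.9 ± 9.24 CPM in Col-0 and 2.05 ± 0.27 CPM in ein2-5. All 18 mitosis genes were higher in ein2-5, also 18 adjusted over the list alone, with a median 1.19 above that of all genes (camera adjusted p = 1.15e-08; adjusted p = 0.225 with an estimated correlation). The anthocyanin enzyme DFR (AT5G42800) rose from 3.598 ± 4.02 CPM in Col-0 to 69.6 ± 15.9 CPM in ein2-5.

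Within the ethylene response list the log2 differences were −3.41 ± 0.28 for ARL (AT2G44080), a regulator of organ size, −3.31 ± 0.247 for ETR2, −2.70 ± 0.113 for the receptor ERS2 and −2.69 ± 0.172 for ARGOS. EBF1, an F-box protein that targets EIN3 for degradation, and ACO1, an enzyme of ethylene synthesis, were the 2 higher members, at 0.98 ± 0.108 and 1.06 ± 0.235. Genes of ethylene synthesis and signalling were lower in 7 and higher in 6 of 17 cases, with the same counts adjusted over the list alone and 8 and 4 after TMM scaling (camera adjusted p = 0.0314; adjusted p = 0.248 with an estimated correlation; 0.0698 after TMM scaling, past the threshold no longer). The ACC oxidase EFE (−2.13 ± 0.188) and the kinase CTR1 (−1.11 ± 0.097) were lower.

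Of 14 flavonoid and anthocyanin genes 12 were higher, also 12 adjusted over the list alone (camera adjusted p = 1.12e-05; adjusted p = 0.225 with an estimated correlation), with DFR at 4.28 ± 0.453, the anthocyanidin synthase LDOX at 4.24 ± 0.448 and the glycosyltransferase UF3GT at 3.61 ± 0.342. Growth lists were higher as well. All 30 ribosomal protein genes (camera adjusted p = 2.08e-10; adjusted p = 0.248 with an estimated correlation) and 24 of 25 ribosome biogenesis genes (camera adjusted p = 8.29e-08; adjusted p = 0.248 with an estimated correlation) were higher. So were 24 of 26 DNA replication genes (camera adjusted p = 3.85e-08; adjusted p = 0.225 with an estimated correlation) and 14 of 16 glycolysis genes (camera adjusted p = 0.000284; adjusted p = 0.248 with an estimated correlation), and adjusted over the list alone these 4 counts were 30, 24, 24 and 14. In the mitosis list KNOLLE, as SYP111, stood at 1.82 ± 0.121 and the anaphase regulator CDC20.2 at 1.54 ± 0.153.

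Starvation genes were lower in ein2-5 in 24 of 28 cases, 25 adjusted over the list alone, with a median of −1.39 relative to all genes (camera adjusted p = 6.96e-17; adjusted p = 0.138 with an estimated correlation). BCAT-2 stood at −3.83 ± 0.263 and ASN1 at −2.81 ± 0.23. Autophagy genes were lower in 10 and higher in 1 of 26, with the same counts adjusted over the list alone, and lower in 18 and higher in 0 after TMM scaling and in edgeR (camera adjusted p = 0.000123; adjusted p = 0.243 with an estimated correlation). Light harvesting genes were lower in 7 of 20, also 7 adjusted over the list alone (camera adjusted p = 0.00277; adjusted p = 0.473 with an estimated correlation). Root and root hair markers were higher in 12 of 14, 13 adjusted over the list alone and 8 after TMM scaling (camera adjusted p = 0.00717; adjusted p = 0.243 with an estimated correlation). Auxin response genes were higher in 8 and lower in 1 of 13, with the same counts adjusted over the list alone (camera adjusted p = 0.0235; adjusted p = 0.225 with an estimated correlation), GH3.3 at 2.00 ± 0.188. Expansin, xyloglucan and cellulose genes were higher in 12 and lower in 2 of 21, with the same counts adjusted over the list alone and 11 and 4 after TMM scaling (camera adjusted p = 0.0421; adjusted p = 0.225 with an estimated correlation). That call ended without Col-0 −Glc 1 (0.0543), ein2-5 −Glc 2 (0.0603) or ein2-5 +Glc 3 (0.0507), and with the replicate block (0.0529). Touch and wounding genes were lower in 7 and higher in 1 of 14, with the same counts adjusted over the list alone (camera adjusted p = 0.019; adjusted p = 0.309 with an estimated correlation), WRKY40 at −2.71 ± 0.407, but not past the threshold after TMM scaling (0.115) or without ein2-5 −Glc 1 (0.0842). Nitrate, sugar transport, low oxygen and clock genes did not pass (camera adjusted p = 0.198, 0.237, 0.263 and 0.198).

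All 11 seed storage and late embryo genes were higher in ein2-5, also 11 adjusted over the list alone, with a median of 4.13 (camera adjusted p = 0.00302; adjusted p = 0.446 with an estimated correlation), and they filled the upper end of the ranking. The late embryo protein gene M17 (AT2G41260) stood at 5.69 ± 1.21, the cruciferins CRU3 (AT4G28520) and CRA1 (AT5G44120) at 5.58 ± 1.26 and 5.54 ± 1.2, and the albumins SESA5 (AT5G54740), SESA2 (AT4G27150) and SESA1 (AT4G27140) at 5.47 ± 0.952, 4.96 ± 0.969 and 4.88 ± 0.82. BGLU19 (AT3G21370) followed at 4.96 ± 0.71, NSP2 (AT2G33070) at 4.58 ± 0.853, the dehydrin RAB18 (AT5G66400) at 4.48 ± 0.789 and LCR67 (AT1G75830) at 4.41 ± 1.04. The albumin genes are near-identical copies, so the split between them is uncertain. The list took between 677 and 1224 CPM in ein2-5 −Glc, and 150, 1.09 and 5.84 CPM in the 3 Col-0 −Glc libraries.

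At the lower end stood THA1 at −4.38 ± 0.164, AZI1 (AT4G12470), a lipid transfer protein of systemic immunity, at −3.47 ± 0.203, the senescence regulator NAC6 (AT5G39610) at −3.43 ± 0.195, and CYP81D8 (AT4G37370) at −3.36 ± 0.412. CRK11 (AT4G23190) followed at −3.18 ± 0.247, the brassinosteroid-responsive transcription factor BEE3 (AT1G73830) at −3.12 ± 0.233, and the ethylene response factor RAP2.6 (AT1G43160) at −3.08 ± 0.169. Limma adjusted p for the 20 genes named by rank lay between 7.83e-09 and 0.00343. In limma 6887 genes were higher and 3121 lower in ein2-5, 1514 and 512 at least by 1 on the log2 scale. The median of all genes lay at 0.15 as deposited and at −0.003 after TMM scaling, where 5135 were higher and 5330 lower, and with the seed list mean as a covariate 3523 and 1195 passed.

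The glucose response in Col-0 and this genotype difference share the Col-0 −Glc libraries. In them 4479 genes were higher in both, 1805 lower in both and 687 opposite, against 2796, 616 and 2625 for independent lists. Across genes, which are not independent replicates, r was 0.479 with covariance 0.263. In 20 simulations all libraries were redrawn as unchanged, so the measured Col-0 −Glc values did not enter. There the mean r was 0.497, the mean covariance 0.0133 and the highest number of genes called in both 0. The covariance exceeded the simulated value by 0.249. The 3 shared control libraries were not split between the contrasts, so the share of these calls owed to them was not determined.

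With glucose, the genotypes still differed in ethylene response, mitosis, anthocyanin and seed genes. Ethylene response genes were lower in 13 and higher in 2 of 17 cases, with the same counts adjusted over the list alone (camera adjusted p = 2.15e-06; adjusted p = 0.0122 with an estimated correlation). ETR2 stood at 58.4 ± 13.0 CPM in Col-0 and 4.49 ± 1.71 CPM in ein2-5. All 18 mitosis genes were higher, also 18 adjusted over the list alone (camera adjusted p = 1.3e-11; adjusted p = 0.139 with an estimated correlation). Flavonoid genes were higher in 12 and lower in 1 of 14, with the same counts adjusted over the list alone (camera adjusted p = 2.01e-06; adjusted p = 0.198 with an estimated correlation), LDOX at 4.49 ± 0.448 and DFR at 4.21 ± 0.453.

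Ribosomal protein genes were higher in 29 of 30, 30 adjusted over the list alone (camera adjusted p = 1.32e-09; adjusted p = 0.439 with an estimated correlation), and DNA replication genes in 20 of 26, 21 adjusted over the list alone (camera adjusted p = 2.46e-05; adjusted p = 0.439 with an estimated correlation). Root markers were higher in 11 of 14, also 11 adjusted over the list alone (camera adjusted p = 0.000106; adjusted p = 0.155 with an estimated correlation), and expansin, xyloglucan and cellulose genes in 9 of 21 with 2 lower, 10 and 2 adjusted over the list alone (camera adjusted p = 0.0195; adjusted p = 0.139 with an estimated correlation). Light harvesting genes were lower in 9 of 20, 8 adjusted over the list alone (camera adjusted p = 0.00386; adjusted p = 0.618 with an estimated correlation), a call that ended without the 3 seed-rich libraries (0.264). Starvation genes were higher in 11 and lower in 5 of 28 (camera adjusted p = 0.375), autophagy genes higher in 4 and lower in 4 of 26 (0.998), and ribosome biogenesis genes higher in 2 and lower in 4 of 25 (0.148), none past camera. Low oxygen genes were higher in 5 and lower in 0 of 10, with a median 1.18 above that of all genes. Their camera adjusted p was 0.05, at the threshold and not past it, and 0.618 with an estimated correlation. After TMM scaling it was 0.0472, past the threshold.

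The 11 seed genes were higher in ein2-5, also 11 adjusted over the list alone, with a median of 5.35, also with SESA2 set at its bound (camera adjusted p = 2.14e-05; adjusted p = 0.439 with an estimated correlation). CRA1 stood at 7.75 ± 1.2, CRU3 at 7.62 ± 1.26, M17 at 7.02 ± 1.21, SESA5 at 6.27 ± 0.952, RAB18 at 6.17 ± 0.789 and LCR67 at 5.86 ± 1.04. The oil body protein gene OLEO2 (AT5G40420) stood at 5.60 ± 0.795, LEA7 (AT1G52690) at 5.48 ± 0.847 and SESA3 (AT4G27160) at 5.43 ± 1.04. SESA2 was listed at 0 in 3 of 3 Col-0 +Glc libraries and at 150.2 ± 140.2 CPM in ein2-5, at least 692-fold higher against a floor of 3 counts per library. The list summed to 132, 2086 and 3148 CPM in the 3 ein2-5 +Glc libraries and to at most 2.9 CPM in Col-0 +Glc, and mitochondrial genes took 0.6%, 2.07% and 3.86% of the reads in those ein2-5 libraries.

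**Figure D4:**
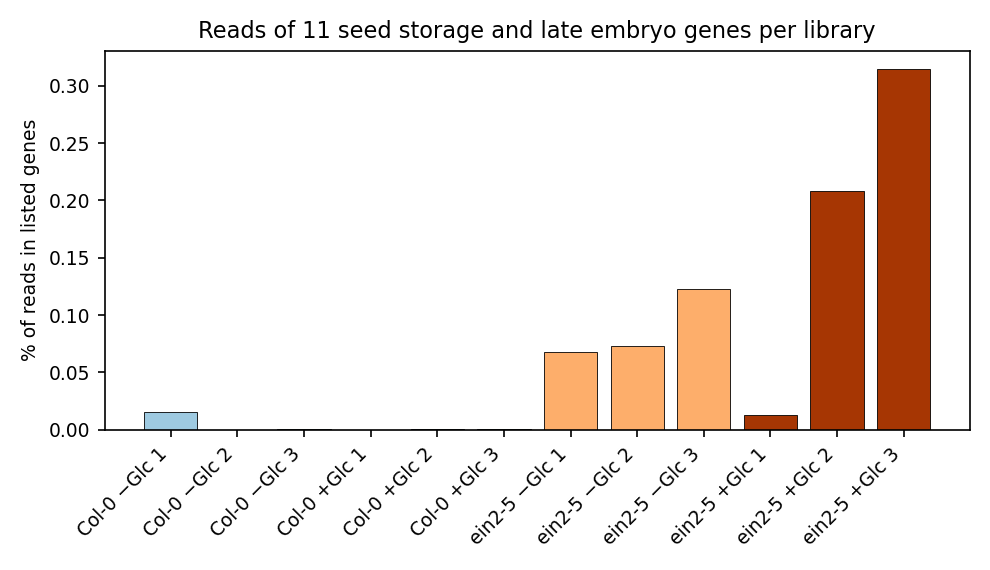
Share of each library's reads, in percent, that fell on the 11 seed storage and late embryo genes; 1 bar per library, coloured by group. The ein2-5 libraries took between 0.0132% and 0.315%, and Col-0 −Glc 1 took 0.015%.

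Named genes lower in ein2-5 were AZI1 at −4.33 ± 0.203 and its neighbour EARLI1 (AT4G12480) at −4.30 ± 0.234, FRK1 at −4.11 ± 0.225, the phospholipase PLA2A (AT2G26560) at −3.47 ± 0.147 and the receptor kinase gene IOS1 (AT1G51800) at −3.27 ± 0.163. BEE3 stood at −3.50 ± 0.233, ETR2 at −3.47 ± 0.247, WRKY49 (AT5G43290) at −3.19 ± 0.252, ARL at −3.13 ± 0.28 and CRK13 (AT4G23210) at −3.10 ± 0.234. Limma adjusted p for the 20 genes named by rank lay between 1.65e-08 and 0.00102. In limma 5100 genes were higher and 4080 lower, 1166 and 652 at least by 1 on the log2 scale. Without the 3 seed-rich libraries 2718 and 1516 passed, and with the seed list mean as a covariate 1171 and 529.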

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

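The results here are those where the effect of glucose differed between the genotypes by a test of the difference itself. Tests chosen only after the results were seen were the share of higher genes after TMM scaling, the TMM and edgeR fits, the fit without the 3 seed-rich libraries and the fit with the seed list as a covariate. Groups of 3 are too small for a test of single outlying libraries, and no data column was left unused.

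Glucose changed 1072 genes more positively and 2606 more negatively in ein2-5 than in Col-0 in limma as deposited, and 1873 and 1794 after TMM scaling. TMM centres the fold changes, with a median of all genes of 0.02 against −0.11 as deposited, so a near-even split follows from it. Whether the excess of negative differences is a scaling effect or real cannot be told apart. Over the genes with an average change of at least 1 on the log2 scale, the median difference in response size was −0.80 for rises and −0.68 for falls, ein2-5 minus Col-0. Over all genes past adjusted p it was −0.30 (exact permutation p = 0.095) and −0.17 (exact permutation p = 0.19), not past the threshold.

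Relative to all genes, the median difference of the responses was 1.75 for the sugar starvation genes, 0.28 for autophagy, −0.17 for ribosomal proteins, −0.85 for ribosome biogenesis, −0.44 for DNA replication, 0.33 for nitrate genes and −0.21 for glycolysis. With an estimated correlation the camera adjusted p of these 7 lists lay between 0.1 and 0.686, so none passed.

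Named genes with a more positive response in ein2-5 were CYP81D11 (3.41), NIA1 (3.27), PPDK (3.23), BXL2 (3.04), NIA2 (2.94), THA1 (2.73), PSK2 (2.66), IAGLU (2.55), ORP4C (2.48) and TDT (2.47). Those with a more negative one were FRK1 (−3.93), NRT2.6 (−3.31), RGF9 (−2.80), NRT2.5 (−2.78), ABCG8 (−2.43), HSFA2 (−2.42), SHB1 (−2.41), CRK5 (−2.34), CSLA11 (−2.27) and CRK12 (−2.22). FRK1, NRT2.5 and CRK12 did not pass in edgeR (adjusted p = 0.483, 0.081 and 0.0695), and FRK1 did not pass in DESeq2 (0.105). PSK2 lay at the floor in ein2-5 in both conditions, so a fall there could not be seen.

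The smaller glucose response of ein2-5 was weighed against 3 explanations. After TMM scaling the median differences were −0.76 for rises and −0.75 for falls, which argues against the deposited scaling as the whole cause, since a scaling factor would move rises and falls the same way. Without the 3 seed-rich libraries they were −0.83 and −0.69, which argues against those libraries as the whole cause, although 1 ein2-5 +Glc library then remains and seed reads in the ein2-5 −Glc libraries are not removed. In ein2-5 without glucose the same genes already lay toward the with-glucose state, by a median of 0.77 for rises and 0.62 for falls, against −0.04 and −0.10 for the genotype difference with glucose. The smaller response may therefore reflect a different starting point more than a different end point, and whether that comes from the seedlings' sugar status, their development or the culture stays open.

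Whether chance can be excluded was asked by relabelling libraries. Of 100 relabellings of the genotypes within each glucose condition, 5 (the real one included) called at least as many genes for the difference of the responses as the real 3678. This count cannot measure chance, so chance is neither excluded nor shown by it. The reason is that exchanging the genotypes in only 1 glucose condition turns the genotype difference itself into a difference of responses. The highest other relabelling called 11684 genes, several times the real count. It kept 3 Col-0 libraries under their label without glucose and 0 with glucose. The others above the real count called 5119, 4878 and 4081 genes and exchanged the genotypes mostly or wholly with glucose, but less or not at all without it. For the 4 pairwise contrasts 10 splits of 6 libraries are too few for a share under 0.05. In each of them 1 of 10 splits, the real one, was as large: 11775 genes for glucose in Col-0 (highest other 0), 8372 for glucose in ein2-5 (4), 10008 for genotype without glucose (0) and 9180 for genotype with glucose (0).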

How the results depend on the processing

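Alternatives chosen only after the results were seen were edgeR on recovered reads, limma after TMM, the 3 seed-rich libraries left out, and the seed list mean as a covariate. Where a setting changed a result the cause was not tested unless stated.

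Asking for an absolute log2 fold change of at least 1 left 2371 higher and 1179 lower genes for glucose in Col-0, 546 and 599 for glucose in ein2-5, 329 and 665 for the difference of the responses, 1514 and 512 for genotype without glucose, and 1166 and 652 for genotype with glucose. This follows from the stricter threshold.

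Scaling for composition shifted all fold changes of a contrast together, which by construction moved calls toward lower for glucose in Col-0 and genotype without glucose, and toward higher for the difference of the responses. Under RLE, DESeq2, edgeR and TMM in this order, genes lower with glucose in Col-0 numbered 5946, 5853, 5843 and 5842. Genes with a more positive response in ein2-5 numbered 1831, 1810, 1776 and 1873, and genes lower in ein2-5 without glucose 5385, 5167, 5306 and 5330. Under RLE the smaller falls in ein2-5 (−0.74) had exact permutation p = 0.05.

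Without the 3 seed-rich libraries 2683 genes were higher and 1729 lower for glucose in ein2-5, 538 and 1276 for the difference of the responses, and 2718 and 1516 for genotype with glucose, and 4077 genes were called the same way in both glucose responses. This leaves 1 ein2-5 +Glc library, ein2-5 +Glc 1, which is assumed to vary like the other groups. It had the fewest seed reads of the ein2-5 libraries. Without it alone 5329 genes were higher and 3675 lower for glucose in ein2-5. The drop in calls therefore cannot be put down to seed reads rather than to which libraries remain. The size differences were −0.83 for rises and −0.69 for falls, each with exact permutation p = 0.05, the smallest that 40 relabellings can give.

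With all 12 libraries, over all genes past adjusted p alone in the average response, the size differences were −0.30 for rises (exact permutation p = 0.095) and −0.17 for falls (exact permutation p = 0.19).

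With the seed list mean as a covariate 3523 and 1195 genes were higher and lower in ein2-5 without glucose, and 1171 and 529 with glucose. The covariate is built from seed genes and follows genotype, so it takes up part of their difference by construction. Without glucose M17 (−0.045), CRU3 (−0.26), CRA1 (−0.028) and LCR67 (−0.49) turned below 0, with glucose M17 (−0.32), LCR67 (−0.41) and SESA3 (−0.80), none past the threshold. For 9 other named gene results the call ended and for 84 it stayed, among them SESA1, BGLU19 and RAB18 without glucose and RAB18 with glucose.

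The replicate block gave the smaller rises in ein2-5 the same value of −0.80 with exact permutation p = 0.125. It ended the call of the expansin, xyloglucan and cellulose list without glucose (camera adjusted p = 0.0529), brought 1 list past the threshold and moved no count of genes by over 1.5 times. The numbers share no documented origin: 11 of 18 pairs of same-numbered libraries had deviations with r over 0.1 (−0.257 to 0.564), and 8 of 12 libraries correlated best with their own number. Between ein2-5 −Glc and ein2-5 +Glc the 3 same-numbered pairs had r over 0.1 (0.564, 0.125 and 0.425). Between the genotypes of a condition, which the permutation exchanges, they had −0.072, −0.16 and 0.194 without glucose and 0.283, −0.009 and 0.311 with glucose.

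Leaving out 1 library at a time gave 7081 to 8162 higher and 3390 to 4071 lower genes for glucose in Col-0, 3826 to 5329 and 2373 to 3675 for glucose in ein2-5, and 741 to 1541 and 1755 to 3429 for the difference of the responses. It gave 5599 to 7259 and 2362 to 3371 for genotype without glucose, 4206 to 5233 and 2967 to 4484 with glucose, and 5687 to 6877 genes called the same way in both glucose responses. The size of the rises went from −0.90 to −0.70, with exact permutation p up to 0.08, and that of the falls from −0.76 to −0.61, with p up to 0.04. The p of the rises passed 0.05 without Col-0 +Glc 1, ein2-5 −Glc 3 or ein2-5 +Glc 1. The calls of named genes stayed in 1200 of 1200 cases, and those of lists in 579 of 588, with 9 ended and 24 gained.

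Camera with an estimated correlation ended 47 of the 49 list calls and left 2, the ethylene response calls in the genotype contrasts. The ethylene response list had an estimated correlation of −0.014, below the preset 0.01. Its camera adjusted p without glucose still went from 5.89e-08 to 0.00577, so a higher correlation was not the reason in that list. The 47 ended calls therefore cannot be put down to correlation between genes alone. TMM and RLE each ended 4 list calls and added 1. The call that TMM added was that of the low oxygen genes between the genotypes with glucose (camera adjusted p = 0.0472). The filter of 1 CPM in 3 libraries (19494 genes), the 150 organelle genes left out, the pseudocount of 0.1 and the fit to only the 2 groups compared changed no call of a named gene and no count by over 1.5 times. The filter of 1 count removed no gene and gives no separate value, and the fit to 2 groups was not run for the difference of the responses. DESeq2 gave no adjusted p for 2 genes.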

Other observations

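The families in this part were grouped by product name and chosen after their values were seen, from 364 families of at least 8 genes. None of those named here passed with an estimated correlation (adjusted p from 0.833 to 0.994). Heat shock proteins rose with glucose in 10 of 12 genes in Col-0 (median 2.02, 1.82 after TMM scaling; camera adjusted p = 0.00889) and in 9 of 12 in ein2-5 (median 1.1; camera adjusted p = 0.00317). Their response was less positive in ein2-5 for 7 genes (median −0.92; camera adjusted p = 0.0125). TCP-1/cpn60 chaperonins rose in 11 of 13 genes in both genotypes, with medians of 0.94 and 0.56 (camera adjusted p = 0.00889 and 0.00523). Proline-rich extensin-like proteins of the cell wall rose in 12 of 13 genes in Col-0 (median 1.37; camera adjusted p = 0.0408) and 11 in ein2-5 (median 1.39; camera adjusted p = 0.00317). Arabinogalactan proteins rose in 18 of 23 genes in ein2-5 (median 0.91; camera adjusted p = 0.000694).

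Between genotypes, histone superfamily genes were higher in ein2-5 in 25 of 28 cases without glucose (median 1.17, 1.04 after TMM scaling; camera adjusted p = 4.13e-07) and in 21 with glucose (median 0.90; camera adjusted p = 3.55e-06). Cysteine-rich receptor-like kinases were lower in 11 and higher in 4 of 22 cases without glucose (median −0.59; camera adjusted p = 0.000994), and lower in 17 and higher in 1 with glucose (median −1.49; camera adjusted p = 1.93e-07). Leucine-rich repeat kinases rose with glucose in 64 of 97 genes in Col-0 and fell in 2 (median 0.58; camera adjusted p = 0.00886), and 34 had a more negative response in ein2-5 (median −0.42; camera adjusted p = 0.000274). Resistance proteins of the CC-NBS-LRR class fell with glucose in 12 of 22 cases in Col-0 and rose in 2 (median −0.43; camera adjusted p = 0.00889), and fell in 13 and rose in 2 in ein2-5 (median −0.54; camera adjusted p = 0.00545).

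Seed storage and late embryo transcripts were present in the ein2-5 libraries at very unequal levels. A candidate source is late or ungerminated seeds among the seedlings: over the 6 ein2-5 libraries the list genes moved together, with a median Pearson r of 0.971 over pairs (lowest pair 0.822). Across the list genes, the Col-0 −Glc library 1 correlated with the mean of the ein2-5 libraries with r = 0.908. An abscisic acid (ABA) response of seedling tissue cannot be told apart as an added source, because 11 measured vegetative ABA genes had a median of 0.50 (quartiles −0.02 and 0.69), with 4 higher and 2 lower, against 4.13 for the seed list; RD29B (2.38) and KIN1 (3.10) were higher and ABI1 (−1.004) lower. Germination was not measured, and no difference between genotype and seed lot was tested.

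More genes rose than fell with glucose in Col-0 as deposited, 67.3% of those called. After TMM scaling, a test chosen after the result was seen, the share was 50.5%. TMM centres the fold changes and so fixes a share near this value, so scaling to the total of the listed genes and a true excess of rises cannot be told apart. The starvation list took between 1.52% and 1.70% of the reads in Col-0 −Glc and between 0.057% and 0.096% in Col-0 +Glc. The 20 genes chosen as most abundant in Col-0 −Glc took between 10.47% and 11.25% there and between 7.78% and 8.41% in Col-0 +Glc. Whether shares of this size account for the median of 0.19 over all genes was not tested. A true rise of most transcripts cannot be read from these values, since no spiked-in standard is described.

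The ein2-5 +Glc libraries 2 and 3 carried 2.07% and 3.86% mitochondrial reads, and their most abundant gene was the mitochondrial rRNA gene ATMG00020. Whether these reads reflect library preparation or the seedlings was not tested. EIN2 reads in ein2-5 remained at 53.5 ± 8.90 CPM without glucose (SD, n = 3), against 129 ± 6.91 CPM in Col-0, and the table cannot show whether the transcript is intact.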
